A study of Danio rerio with 6 samples.

How the data were processed

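Total RNA, extracted with Trizol per the labels' protocols, was measured on 6 Affymetrix zebrafish arrays, 3 of embryos kept in DMSO and 3 of embryos kept in leflunomide at 6.5 uM. Groups and replicate numbers came from the sample titles. The deposited table holds log2 values, which the authors summarised with GCRMA per the submitters' processing notes. GCRMA corrects probe intensities for background by their sequence, normalizes arrays by quantiles and gives 1 log2 value per probe set; its version is not given in the sources used here. The deposited values are centred: the median of every probe set over the 6 arrays is 0 within 5e-07. No source used here states that step. It leaves differences between arrays as they were and removes the absolute level. The medians of the arrays in the table are -0.0137, -0.0230 and 0.0081 for DMSO 1 to 3 and 0.0052, 0.0095 and 0.0180 for leflunomide 1 to 3. The direction was taken from the titles, and all differences are leflunomide minus DMSO. The log base is not stated; it was taken as 2 because GCRMA gives log2 values.

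A coarse level was recovered from the rounding of the values. Single-precision numbers have a step that doubles when the level crosses 4 or 8, and 100.0% of probe sets fell on the step of levels of 2 or more. Values under 0.001 in size were not read. By this step, 2800 probe sets had a median level of 2 to 4, 8529 of 4 to 8 and 4173 of 8 to 16. The plan, fixed before the data were examined, had assumed uncentred values and kept probe sets with a log2 value of at least 4 on at least 3 arrays. The recovered level of at least 4 took the place of that filter. The level on a single array was bounded by the band of the median and the distance of the array from the median. Of 15617 probe sets, 115 were array controls and were left out, and 12702 were tested.

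The annotation of the platform named 1 gene for 10795 of the 15502 other probe sets, several for 135 and none for 4572. Only probe sets with 1 gene were named. Of their gene identifiers, 10718 were found in the RefSeq gene table of the assembly GRCz12tu, which updated 1 symbol; no coordinates were used. A probe set with a close paralog can bind its transcripts too. For list tests each gene had 1 probe set, that with the highest recovered level, then the most specific suffix, then the ID, in place of the planned highest mean. Among 1249 genes with several tested probe sets, 88 had all called alike, 246 some called, 912 none, and 3 (kif2c, tspy and lrrfip1a) had calls in opposite directions.

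Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05. The limma and gene list tests are two-sided. Gene lists, 26 in number and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 over 7838 genes, adjusted over the 26 lists. camera called 10 lists with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05). fry, which asks whether the genes of a list move in 1 direction, without comparing them with other genes, called 14. The genes named in the text were those of a rule fixed beforehand: the 12 largest increases and 12 largest decreases among called probe sets whose groups did not overlap, 1 per gene and with a regular gene symbol, the up to 4 members of each list with the lowest adjusted p, and dhodh, crestin, sox10, foxd3, mitfa, dct, tyr, mdm2, cyp1a and supt5h, among others fixed beforehand, where measured. The result of 1 list is not reported here, though the counts of lists include it. Exceptions are marked in the text. Medians, means and tests of the lists differed in sign in some lists that were not called, among them xanthophore and iridophore (median 0.01, mean -0.75) and pyrimidine metabolism (median 0.06, mean -0.10).

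The procedure was tested on simulated data for the leflunomide against DMSO comparison, with 50 of 12702 probe sets changed by each of 4 sizes. It recovered 18.0% of probe sets changed by 0.5 on the log2 scale, 68.0% of those changed by 1 and 100.0% of those changed by 2 or 4, with 9 false calls, and 0 calls when nothing was changed. Far fewer probe sets were changed there than the 20.6% called in the data, so these recovery rates do not carry over to the real fit. Noise was drawn independently for each probe set and array, so effects shared within an array were not simulated. A permutation test of 2 groups has a smallest two-sided p of 0.10 with 3 arrays against 3, so no such test is given for single genes. No 2 arrays shared an identical value in any probe set. Alternatives covered the filter, the scaling between arrays, the variance model, array weights, the replicate number as a block, each array left out, stricter thresholds, 1 value per gene and other list tests. Neither batch nor date was given in the labels used here.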

Results

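Transcript levels were measured in zebrafish embryos of the Tu strain that had been kept in leflunomide at 6.5 uM, or in the solvent DMSO, from 50% epiboly, a stage of gastrulation, until 24 hours after fertilization. Leflunomide is an antirheumatic drug whose active form inhibits dihydroorotate dehydrogenase, an enzyme of pyrimidine synthesis. Each group held 3 arrays of total RNA, so 6 Affymetrix zebrafish arrays carried 15617 probe sets each. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate clutches, so the p-values measure only the spread between these samples, which may be technical. Every value is a log2 difference, and no absolute level is given beyond the coarse one recovered for the filter. The comparison asks which transcripts differed after leflunomide, and in particular what happened to the neural crest, the embryonic cell population that gives rise to pigment cells, and to its derivatives.

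After leflunomide the 12 largest decreases of named genes included genes of fast muscle (myhz1.3, pvalb2, tnni2a.4), red blood cells (slc4a1a, hbbe3, hbae3) and pigment synthesis (gch2), and the largest increase was that of cyp1a. Of 12702 probe sets tested, 1248 were higher and 1370 lower after leflunomide at an adjusted p under 0.05 in limma, together 20.6%. At least 2-fold changes were more often decreases: 136 called probe sets were higher and 494 lower by that much, and 8 were higher and 88 lower by at least 4-fold. Expressed by gene, 879 genes had a higher probe set and 914 a lower one among 7838 tested. The 3 leflunomide arrays lay entirely above or below the 3 DMSO arrays for 40.8% of all tested probe sets, where chance gives 10%. The main component of variation between arrays, 69.1% of the total, separated the DMSO arrays, at -30.0 to -28.5, from the leflunomide arrays, at 14.4 to 37.3. Leflunomide array 1 changed less than the others, with a median absolute log2 change of the called probe sets of 0.55, against 0.76 and 0.71 on arrays 2 and 3. The counts depended on single arrays. They fell to 540 higher and 760 lower without DMSO array 1, to 525 and 718 without DMSO array 2, to 421 and 712 without DMSO array 3, and to 639 and 834 without leflunomide array 2.

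Several neural crest transcripts fell. Of 17 tested genes of the neural crest list, 8 fell, 0 rose and 9 did not pass the test; adjusted over the list alone, 10 fell. crestin, a pan-neural crest transcript of zebrafish, fell by 3.25 on the log2 scale (SE 0.31, 9.53-fold, limma adjusted p = 0.0011, n = 3 and 3). foxd3, a transcription factor of early crest, fell by 1.54 (SE 0.15, adjusted p = 0.00122). twist1a fell by 1.29 (SE 0.10, adjusted p = 0.000458), with an SD of 0.006 over the leflunomide arrays. sox10, which is required for pigment cells and peripheral glia, fell less, by 0.91 (SE 0.10, 1.88-fold, adjusted p = 0.00185). All 4 were called in each of the 6 fits that left out 1 array. Another of the 8, sox9b, lost its call in 5 of those fits and with the mean over its probe sets. Genes not called, named after their values were seen, included tfap2a (-0.23), snai2 (-0.18), tfap2c (0.10), ets1 (-0.02) and snai1b (-0.002). The list as a whole shifted down against the other tested genes by limma's camera test (adjusted p = 6.17e-05), and this call was lost with an estimated correlation (adjusted p = 0.279). The median of the list was -0.26 on leflunomide array 1 and -0.64 and -0.57 on arrays 2 and 3.

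Melanophore genes were measured in small number, and 4 of the 6 tested fell, with 0 higher; adjusted over the list alone, 5 fell. mitfa, the transcription factor that specifies melanophores, fell by 2.15 (SE 0.13, 4.43-fold, limma adjusted p = 0.00018). dct, an enzyme of melanin synthesis, fell by 2.94 (SE 0.22, 7.68-fold, adjusted p = 0.00048). tspan36 fell by 0.50 and rab32a by 0.59, and both calls depended on single arrays: tspan36 was lost without any 1 of the DMSO arrays, rab32a in 5 of 6 such fits. tyr, the tyrosinase gene, had a log2 difference of -0.05 (SE 0.10, adjusted p = 0.761). The list shifted down in camera (adjusted p = 0.000263; adjusted p = 0.279 with an estimated correlation). In the xanthophore and iridophore list, gch2, an enzyme of pteridine pigment synthesis, fell by 5.07 (SE 0.15, 33.6-fold, adjusted p = 4.47e-06) at one probe set and by 1.35 at the other. In that list 2 of 7 tested genes fell and 1, gart of purine synthesis, rose (log2 0.49, adjusted p = 0.0447), a call lost in 4 of the 6 fits that left out 1 array and with 75th percentiles aligned. The same counts held adjusted over the list alone, and the list was not called by camera (adjusted p = 0.277).

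**Figure D1:**
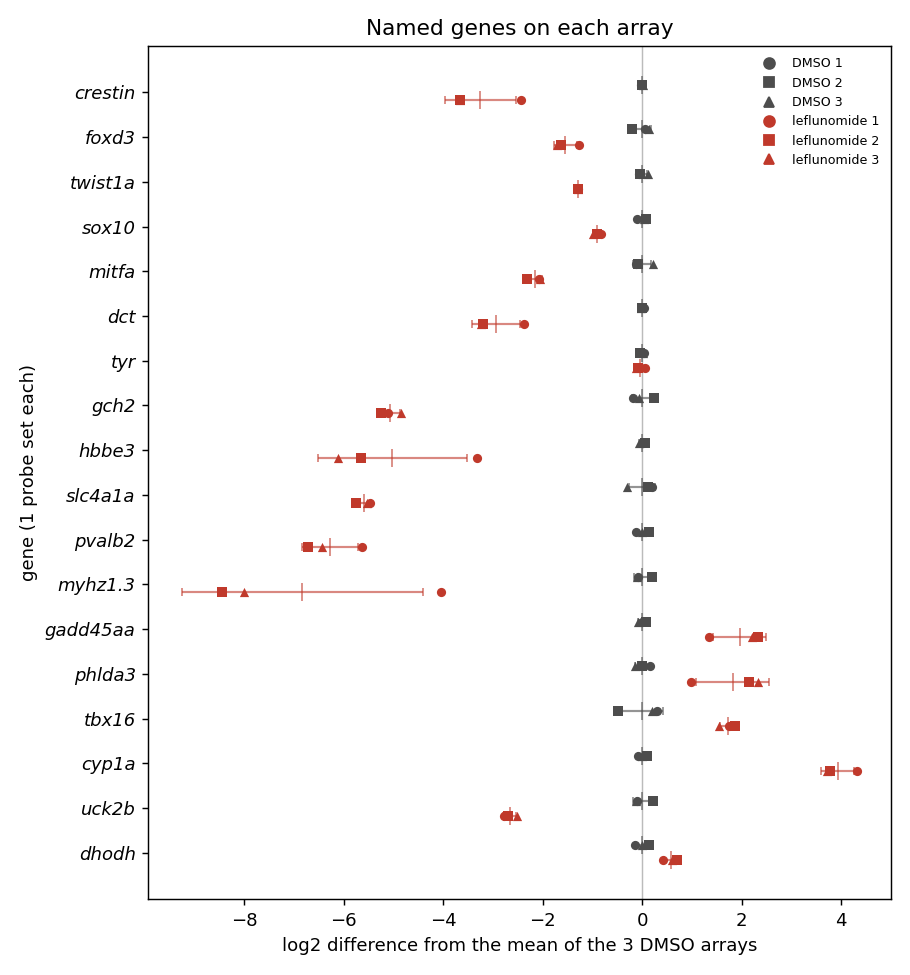
Selected genes on each array. The x axis is the log2 difference from the mean of the 3 DMSO arrays, points are arrays, and ticks with bars are the group mean and SD (n = 3). The leflunomide arrays of mitfa lie between -2.31 and -2.05, those of cyp1a between 3.71 and 4.31, and those of tyr overlap DMSO.

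Muscle genes showed the largest shift of any list. Of 27 tested skeletal muscle genes, 24 fell and 1 rose, with the same counts adjusted over the list alone. myhz1.3, a fast myosin heavy chain, fell by 6.83 (SE 1.02, 114-fold, limma adjusted p = 0.00488), from -4.05 on leflunomide array 1 to -8.44 on array 2. pvalb2, a parvalbumin of fast muscle, fell by 6.27 (SE 0.26, 77.1-fold, adjusted p = 2.54e-05). tnni2a.4, a fast troponin I, had log2 changes of -5.85 (SE 0.32) and -5.39 (SE 0.16) at its 2 probe sets, both called. At the first, the level on leflunomide array 2 was at most 4.12, so its value may be near the lowest that the array can measure and the fall may be larger than given. The same may hold for other large falls, whose levels are known only within wide bounds. The called log2 changes of mylpfa, mylz3, myl1, tnnt3a, pvalb1 and myoz1b ranged from -4.53 to -3.18. The 1 muscle list gene that rose was myf5, an early myogenic factor (log2 0.81, SE 0.18, adjusted p = 0.019), named here after its value was seen. The list had camera adjusted p = 2.3e-19, and adjusted p = 0.279 with an estimated correlation. Its median was -1.37 on leflunomide array 1 and -1.98 and -2.26 on arrays 2 and 3. RNA quality controls also differed: the difference between 3' and 5' control probe sets was higher by 1.24 for acta1 after leflunomide and changed by -0.66 for gapdh. These control transcripts fell themselves: the acta1 controls, annotated to the muscle list gene actc1b, had log2 changes of -1.39 (3') and -2.62 (5'), and the gapdh controls of -1.80 (3') and -1.15 (5'). All 4 spike-in controls had their highest 3' minus 5' difference on leflunomide array 3, from 0.49 to 1.91 against 0.37 at most in DMSO. On leflunomide arrays 1 and 2 these differences ran from -0.31 to 0.19. In the cardiac list, 0 of 9 tested genes passed in limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 (list adjusted p = 0.7). The genes cmlc1 and myl7 varied widely among the leflunomide arrays, from 0.12 to -3.12 and from 0.19 to -2.18.

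Red blood cell genes fell as well, with 11 of 16 tested lower and 0 higher; adjusted over the list alone, 13 were lower and 1 higher. slc4a1a, the red cell anion exchanger, fell by 5.59 (SE 0.15, limma adjusted p = 4.47e-06). The embryonic globins hbbe3, hbae3 and hbbe2 had called log2 changes of -5.03 (SE 0.63), -4.37 (SE 0.41) and -2.61 (SE 0.26). The other hbae3 probe set, which stands for the gene in the list test, had a called change of -4.05 (SE 0.39), and its DMSO arrays agreed to an SD of 0.000, as saturated values could, in which case the fall is understated. The heme enzyme gene fech fell by 0.92 (SE 0.10). aqp1a.1, an aquaporin gene, fell by 3.36 (SE 0.62, adjusted p = 0.0108), a call lost without DMSO array 3. The erythroid list was shifted down in camera (adjusted p = 5.04e-09; adjusted p = 0.171 with an estimated correlation). Among leukocyte genes, lyz, which encodes lysozyme, fell by 2.43 (SE 0.20, adjusted p = 0.000738), the only 1 of 10 called in either adjustment, and the list was not called (adjusted p = 0.569). Of 8 endothelial genes, tie1, erg and fli1 fell by 0.67, 0.69 and 1.19, with -0.17 at the other fli1 probe set, each call lost without at least 2 of the DMSO arrays. Adjusted over the list alone, 6 endothelial genes were lower and 1 higher. The endothelial list had camera adjusted p = 0.0224, adjusted p = 0.502 with an estimated correlation, and adjusted p = 0.0538 in fry.

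Nervous system genes were lower at both neuronal and progenitor level. In the neuronal list 14 of 26 tested genes fell and 0 rose; adjusted over the list alone, 18 fell. neurog1 and ascl1b, factors that start neuron formation, fell by 0.95 (SE 0.10) and 0.99 (SE 0.13), neurod4 by 0.85 (SE 0.12), and the tubulin gene tubb5 by 1.19 (SE 0.13) at one probe set. The other tubb5 probe set had a value of -0.34. The neuronal list median was -0.39 on leflunomide array 1 and -0.96 on each of arrays 2 and 3. Of 26 neural progenitor genes, 9 fell and 0 rose; adjusted over the list alone, 13 fell and 1 rose. dlb, a Notch ligand, fell by 1.71 (SE 0.15) at one probe set, with -1.04 at the other, fabp7a, a radial glia gene, by 2.35 (SE 0.35), pax6a by 0.89 (SE 0.10) and zic1 by 0.83 (SE 0.14). camera called the neuronal list (adjusted p = 1.5e-08) and the progenitor list (adjusted p = 0.00259). With an estimated correlation these became adjusted p = 0.393 and adjusted p = 0.279. In the eye, the lens crystallin genes crybb1 and cryba4 fell by 2.17 (SE 0.21) and 1.77 (SE 0.16), 2 of 4 tested lens genes (list adjusted p = 0.264); adjusted over the list alone, the same number fell and 1 rose.

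DNA replication genes fell, and mitosis genes did not move as a list. Of 38 tested S phase genes, 14 fell and 1 rose; adjusted over the list alone, 15 fell and 1 rose. The subunits of the replicative helicase mcm5, mcm4 and mcm3 were 2.95-fold, 2.40-fold and 2.14-fold lower (log2 SE 0.18, 0.19 and 0.12), and the clamp loader gene rfc4 fell by 0.62 (SE 0.11). The 1 S phase gene that rose was cdc45 (log2 0.60, adjusted p = 0.011), named after its value was seen. camera called the S phase list (adjusted p = 0.000588; adjusted p = 0.502 with an estimated correlation). In the mitosis list 4 of 29 tested genes rose and 0 fell in either adjustment: birc5a, cks1b, mad2l1 and bub3, by 0.52 to 0.71. Each of these 4 calls was lost in 2 to 5 of the 6 fits that left out 1 array. The mitosis list had adjusted p = 0.264, and it passed without leflunomide array 1 (adjusted p = 0.0348).

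Genes of pyrimidine metabolism, the pathway of the drug's target, moved in both directions, with 3 higher and 3 lower among 16 tested, and 4 higher and 5 lower adjusted over the list alone. uck2b, a uridine-cytidine kinase of the salvage pathway, fell by 2.66 (SE 0.13, 6.34-fold, limma adjusted p = 7.12e-05), to nearly equal extent on the 3 leflunomide arrays (-2.78, -2.70 and -2.52). uckl1b fell by 0.79 (SE 0.11). dhodh itself rose by 0.58 (SE 0.12, 1.49-fold, adjusted p = 0.0171), and the call was lost without DMSO array 1, DMSO array 3 or leflunomide array 2. cad, which encodes the enzyme of the opening steps of pyrimidine synthesis, rose by 0.79 (SE 0.16, adjusted p = 0.0158), a call lost without DMSO array 1 or 2. The list had adjusted p = 0.7 in camera.

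The largest increase was that of cyp1a, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, which rose by 3.93 (SE 0.17, limma adjusted p = 3.24e-05). sult6b1, a sulfotransferase gene, rose by 1.55 (SE 0.22, adjusted p = 0.00403), and sox9b fell by 0.56, a call lost in 5 of 6 fits without 1 array and with the mean over its probe sets, the other of which had a value of -0.13. These were the 3 called among 9 tested genes of the aryl hydrocarbon receptor list, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.456). ahr2, the receptor gene, had a value of -0.41 (adjusted p = 0.0962). The other large increases were ptgdsb.2 (log2 3.86, SE 0.45) and ptgdsb.1 (1.78, SE 0.36, lost without any 1 DMSO array), which encode prostaglandin D synthases. fosab, an immediate early gene, rose by 3.00 (SE 0.35) at one probe set and had values of 0.89 and 0.92 at 2 others. mvb12ba rose by 2.31, gadd45aa, a growth arrest gene, by 1.96 (SE 0.24, limma adjusted p = 0.0025), phlda3 by 1.82 (SE 0.33, adjusted p = 0.00948, lost without DMSO array 3), zp2.6 of the egg coat by 1.94, fn1b, a fibronectin, by 1.86, bmb by 1.67 and sptan1 by 1.66, with -0.13 at the second sptan1 probe set. The ID of the sptan1 probe set that rose shares its stem with a probe set annotated to a2m3g, at a level under 4. That probe set also rose (log2 1.08, limma adjusted p = 0.00797), so which transcript was measured is uncertain. mdm2, a ubiquitin ligase gene, had a log2 difference of 0.47 (SE 0.15, adjusted p = 0.0647).

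Presomitic mesoderm genes split by direction. Among 21 tested, 5 rose and 5 fell (6 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.678). tbx16 and cdx4, transcription factors of the tail bud, rose by 1.71 (SE 0.21) and 1.63 (SE 0.21), with 0.87 at the other tbx16 probe set, and mespaa rose by 0.77 (SE 0.12). lfng, a modulator of Notch, fell by 0.99 (SE 0.12). In the notochord list 2 of 14 rose, ntd5 by 0.80 and noto by 0.45, the latter lost in all 6 fits without 1 array, with either scaling between arrays and with array weights, and 1 rose adjusted over the list alone (list adjusted p = 0.613).

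Genes of the integrated stress and heat shock list fell more often than they rose, 6 against 1 of 21 tested, and 8 against 2 adjusted over the list alone. atf4b and atf4a, factors of the amino acid response, fell by 1.33 (SE 0.11) and 1.17 (SE 0.15), and hsp90aa1.1, a chaperone abundant in muscle, by 1.62 (SE 0.20). chac1, an ATF4 target, was 2.29-fold lower (log2 SE 0.12, adjusted p = 0.0012). The list had camera adjusted p = 0.00924, adjusted p = 0.279 with an estimated correlation, and adjusted p = 0.18 among probe sets at a level of at least 8, a filter added after seeing the data. Of the transcription elongation genes, 2 of 27 rose and 1 fell (1 and 0 adjusted over the list alone; list adjusted p = 0.633). hexim1, an inhibitor of the elongation kinase, rose by 0.88 (SE 0.10, limma adjusted p = 0.00169). supt5h had a value of 0.27 (SE 0.11, adjusted p = 0.121), and the calls of polr2a (0.46) and ccnt2b (-0.42) were each lost in 5 of 6 fits without 1 array and with the replicate block, that of polr2a also with 75th percentiles aligned and with the mean over its probe sets. Of 63 ribosomal protein genes, 0 passed in limma in either adjustment and 0 at an unadjusted p under 0.05, with a list median of -0.00 and adjusted p = 0.715. In the ribosome biogenesis list 2 of 37 fell, dkc1 by 1.02 (SE 0.16) and ncl by 0.36, the latter lost in 5 of 6 such fits and with the replicate block, and 1 fell adjusted over the list alone (list adjusted p = 0.781).

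The remaining tissue lists were not called by camera. Of 20 epidermal genes, anxa1b (0.70) and anxa1c (0.46) rose and atp1b1b fell by 1.65; adjusted over the list alone 4 rose and 3 fell (list adjusted p = 0.456). The call of anxa1c was lost in 5 of 6 fits without 1 array, with either scaling between arrays and with array weights. Of 22 yolk and endoderm genes, 3 rose and 2 fell in either adjustment, among them fabp2 at 0.57 (SE 0.11) and rbp4, which fell by 1.06 (SE 0.18; list adjusted p = 0.264). In the hatching gland list klf17 fell by 0.62 (SE 0.11) and agr2 by 1.07 (SE 0.31), the latter lost in 5 of 6 fits without 1 array, with no filter and with a robust prior with a trend, 2 of 4 tested in either adjustment (list adjusted p = 0.569). In the pronephros list 1 of 12 fell, slc20a1a by 0.79, lost in 5 of 6 such fits, and 0 passed adjusted over the list alone (list adjusted p = 0.392).

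**Figure D2:**
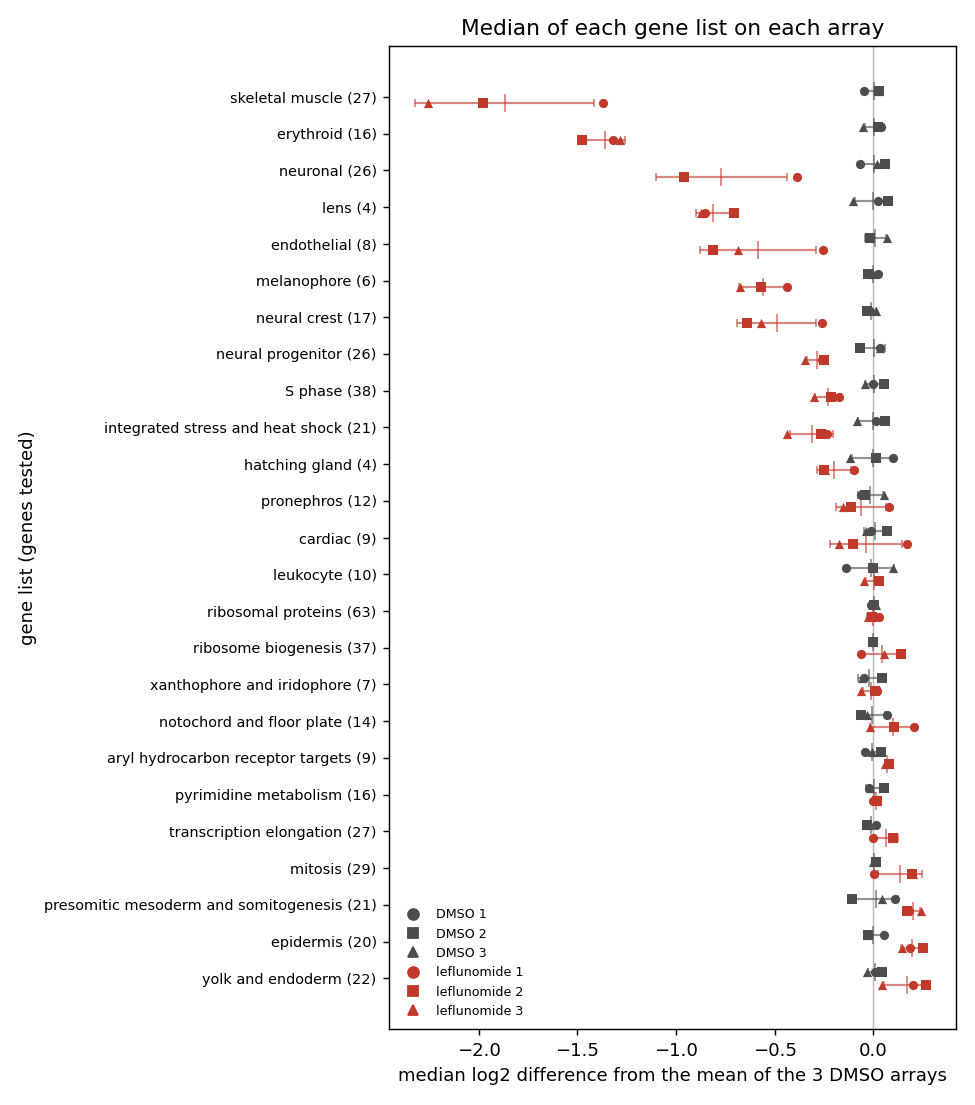
Median of gene lists on each array. The x axis is the median log2 difference of the list's tested genes from the mean of the 3 DMSO arrays, the number in brackets is the number of genes tested, points are arrays, and ticks with bars are the group mean and SD of the medians (n = 3). Skeletal muscle lies between -2.26 and -1.37 on the leflunomide arrays, and ribosomal proteins lie near 0.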

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

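The tests of leflunomide array 1, of RNA breakdown, of slower development and of egg transcripts were chosen after the results were seen. The counts over other splits of the arrays were planned before their results were seen.

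Probe sets outside the comparison also moved. Among the 2800 dim probe sets at a level under 4, 30 were higher after leflunomide and 81 lower in a limma fit of the whole table. The largest increases were a further probe set of fosab (log2 2.36, SE 0.34, adjusted p = 0.00512) and one annotated to mpx (2.03, SE 0.16, adjusted p = 0.000772), whose ID shares its stem with the cyp1a probe set. Another dim probe set annotated to mpx was lower (log2 -0.41, SE 0.11, limma adjusted p = 0.0385). Among the 115 control probe sets, 3 were higher, each at the 3' end of a spike-in (log2 0.43 to 0.51), and 7 lower, of the acta1 and gapdh controls.

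In the counts of called probe sets, the real grouping gave 2618 and the highest of the other splits gave 0, so 1 of the 10 splits reached the real count. For gene lists the real grouping called 10, and the highest other split called 12; 3 of the 10 splits, the real one included, called at least 10. The other splits still place unequal numbers of leflunomide arrays on their sides. With 10 splits the share cannot be under 0.05.

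Leflunomide array 1 changed less than arrays 2 and 3: its median share of their change was 49.3% for the 14 called neuronal genes and 74.7% for the 14 called neural crest and pigment genes, which did not differ past the threshold (permutation test p = 0.13). That permutation exchanged genes measured on the same arrays, so its p-value does not measure the spread between samples. DMSO RNA mixed into that sample is argued against only at the share that the neuronal genes would need, 37.5%, which limits any fall to -1.42. The 34 probe sets that fell over 8-fold on arrays 2 and 3 had a median of -3.06 on array 1, with 31 beyond the limit. They were called in a fit that included array 1, which favours probe sets that also fell there. The neuronal list had the lowest share on array 1 of the lists compared, so a smaller mixed share is not excluded. A compressed scale, at a common share of 62.2%, was not settled for the set, though normalization by quantiles already equalizes the scales of arrays. Of probe sets that rose over 2-fold, 2.9% (6 of 208) changed more on array 1 than that share gives, by over 3 standard errors, and 9 changed less. Of those that fell, 7.5% (48 of 639) changed more and 62 less, and the floor can hide differences in falls. Single genes went against a compressed scale, with cyp1a at 4.31 on array 1 and 3.77 and 3.71 on the others, and sult6b1 at 1.99 and at 1.27 and 1.39. A weaker response of those embryos was not tested.

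Muscle, blood and neuronal genes were lower. RNA breakdown may contribute and stays open: the difference between 3' and 5' control probe sets moved by 1.24 for acta1 and by -0.66 for gapdh, opposite directions, and both control transcripts fell themselves. The value of gapdh on leflunomide array 1, at -0.18, lay close to the lowest DMSO array, at -0.15. All 4 spike-in controls, added to the RNA and not from the embryo, had their highest 3' minus 5' difference on leflunomide array 3 (DapX 1.91, ThrX 0.85, PheX 0.58 and LysX 0.49), against 0.37 at most in DMSO. On leflunomide arrays 1 and 2 their differences ran from -0.31 to 0.19, while the muscle list median was -1.37 and -1.98. The spike-in shift of array 3 therefore does not account for the falls on arrays 1 and 2. Slower development could also lower such genes. The presomitic list, which would then be higher, gave adjusted p = 0.678 with members moving both ways, so delay and a direct effect of the drug cannot be told apart. RNA breakdown and delay could likewise apply to the falls of neural crest and pigment genes.

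Egg coat genes rose: 13 of 14 tested probe sets were higher after leflunomide, with median log2 changes of 0.73, 1.16 and 1.40 on the 3 leflunomide arrays, and several of them match more than 1 zp2 copy. Egg material in the samples may contribute and stays open. All 13 other egg transcripts tested had positive log2 differences, from 0.07 to 1.04, but only 1, npm2b, passed the limma test. They came from a list of 16 genes, so egg transcripts outside that list were not part of the comparison. Of all tested probe sets, 55.9% had positive differences (exact binomial test, one-sided p = 0.00052). The binomial test counts transcripts measured on the same arrays as independent, so a shift shared within arrays could make all 13 positive. Its p-value does not measure the spread between samples. The median of these 13 transcripts, 0.25, was below that of the egg coat genes (permutation test p = 0.002). The permutation exchanges probe sets, several of which match the same zp2 copies, and was chosen after the egg coat rise was seen. Neither p-value therefore decides whether egg material was present. How abundant each transcript is in eggs against embryos is not known from centred values. Binding of the probe sets to transcripts of other zp copies was not tested, and a response to the drug remains a hypothesis.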

How the results depend on the processing

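The filter at a level of at least 8 was chosen after seeing the data. Centring left no level for the planned filter at 6, quantile normalization and floor at 4, which were not run, and under 2 melanophore genes passed the level of 8. Among probe sets, 676 higher and 529 lower passed that filter, which tests fewer; 136 and 494 changed by at least 2-fold; 294 and 575 had adjusted p under 0.01. Leaving out 1 array gave 421 to 1385 higher and 712 to 1444 lower. With fewer arrays the test has less power, yet without leflunomide array 1 the total rose to 2829. All other settings stayed within 1.5 times the main counts. Every main call that was fitted again kept its sign under the settings that test probe sets. This was nearly fixed beforehand when 1 array was left out, since the groups did not overlap for 2616 of the 2618 calls. The share of higher calls was 47.7% as deposited and 43.3% or 38.2% with array medians or 75th percentiles aligned. The same-numbered arrays had correlations of their deviations of 0.33, 0.19 and 0.07. Other pairs between the groups ranged from -0.23 to 0.05. For 6 of 6 arrays the best correlation with the other group was with their own number. Deviations were taken from the mean of each group, so these 6 matches are not independent. For leflunomide array 3 the margin was small, 0.07 against 0.05 with DMSO array 2. The matches are a weak hint from the data that the numbers pair the arrays, and the main fit used no such pairing. The replicate block gave 1259 higher and 1300 lower, and 2232 of the 2618 calls were shared.

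With an estimated correlation the neural crest list and the melanophore list had adjusted p = 0.279, and 0 of the other lists were called, against 8. The cause was not tested. The integrated stress and heat shock list had an estimated correlation of 0.018, near the preset 0.01, yet its unadjusted camera p went from 0.0032 to 0.05. The size of the correlation alone therefore does not explain the loss of that call. For the other lists too, a call lost under this option need not be due to correlation between genes alone. In all other settings 6 to 12 of the other lists were called, the neural crest list ranged from 8.66e-06 to 0.00451 and the melanophore list from 0.000204 to 0.00282. fry also called 5 lists that camera did not (xanthophore and iridophore, pyrimidine metabolism, aryl hydrocarbon receptor, transcription elongation and lens). Of 94 called probe sets of named genes, 69 were called in all 6 fits that left out 1 array. Among the 94, 0 reversed under any setting, which says little where the groups do not overlap.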

Other observations

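These values were picked after they were seen. Among egg coat genes, zp3a.2 rose by 1.59 (SE 0.22, limma adjusted p = 0.00377) and zpax4 by 1.58 (SE 0.23, adjusted p = 0.00459), while zar1, an egg transcript, had a log2 difference of 0.25 (SE 0.10, adjusted p = 0.108). Among dim probe sets, chka, a choline kinase gene, had a log2 difference of -2.13 (SE 0.24, adjusted p = 0.00235) and uck2a, the paralog of uck2b, had a log2 difference of -1.06 (SE 0.16, adjusted p = 0.00552).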
